A study of Candida albicans with 6 samples.

How the data were processed

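RNA-seq was run on Candida albicans SC5314 grown in RPMI medium with or without the compound H55. Per the labels, cells received 8 µM H55 or no compound and were harvested after 6 h, RNA was extracted with a kit for yeast, and libraries followed standard Illumina steps. Sequencing was on an Illumina HiSeq X instrument, per the series' design text. The 6 samples form 2 groups named in the labels, untreated and H55, with 3 replicates each. The aligner, the counting program, the genome build, the annotation and the strand setting are not given in the sources used here.

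Each deposited file holds 1 value per gene for 1 library, under a header that names no unit. The deposited values were taken as FPKM, that is reads scaled by gene length and by the assigned reads of the library, because they are not whole numbers, sum to different totals in the libraries, and fall on whole multiples of a single step per library once multiplied by gene length. Whether reads or fragments were counted cannot be read from the values, and both are called reads here. No between-library normalisation by the authors was visible in the deposited FPKM values. Each file lists 6305 genes under locus tags. Of these, 6263 matched the RefSeq gene table of assembly ASM18296v3, which supplied symbols, gene types and lengths, and the other 42 carry names of unannotated genes. Because no build is named for the files, no coordinates are given. Of its protein-coding lengths, 95.7% are multiples of 3, so they are coding lengths without untranslated regions.

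Depth was recovered from the low values. Value times RefSeq length gave whole reads in all 6 libraries, within a tolerance of 0.02 reads, for 5843 genes (93.3% of the matched genes). A further 409 genes were given the length that makes their values whole, and 53 genes were left without reads. The recovered reads added up to between 100.0% and 100.02% of the depth read from the step. Depth was 37456782 to 47452006 reads per library, so that 1 read in a gene of 1 kb was worth 0.0211 to 0.0267 FPKM. The recovered reads were used only for depth, shares of reads, the check for duplicated libraries, the ratio given for OP4 and 1 alternative test.

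The design fixed before the data were examined assumed a count table and named a fallback for normalised values. Since the files hold FPKM values, count models were not used and the fallback became the main test. Genes with at least 1 FPKM in at least 3 libraries were kept (5993 genes, with 312 left out). Values were taken as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 was fitted to the 2 groups with a mean-variance trend, leaving 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. A log2 fold change is H55 minus untreated.

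Gene lists for 28 processes were written before the data were examined, from general knowledge of Candida albicans and not from these samples. They name 898 members, of which 839 were found by symbol, and symbols without a match were left out. The list of cytosolic ribosomal proteins was a rule on symbols, and its members count as found. For each list, members past the threshold were counted from the adjustment over all tested genes and again adjusted over the list alone. Each list was compared with all other genes by camera in limma with a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. Camera p-values were adjusted over the 28 lists.

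Genes were named by a rule fixed before the data were examined. Its first part takes the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a log2 fold change of at least 1 in size, libraries of the groups that do not overlap, a mean of at least 10 FPKM and a symbol. The second part takes up to 4 members of each list with the smallest p past the threshold, or the 2 with the smallest p where fewer than 2 pass. The third part is a set of sterol and filamentation genes named whatever their values, and the fourth is the 3 genes with the highest mean level in each group. The rule named 131 genes, of which some are not reported here. Other list members were named where a group had 5 members or fewer, as was ERG251 beside ERG25. The text says that they were chosen after their values were seen. Members of families by symbol prefix, in the closing section, were likewise chosen after their values were seen.

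Replicates were compared before averaging. A chi-square over genes with at least 50 reads gave at least 71.26 per gene for every pair of libraries, far above sampling noise, so no library was counted as a duplicate. The fit was first tested on simulated data drawn for the comparison of H55 with untreated, with 5970 genes tested. All 50 genes were recovered at each of the true folds 2, 4, 0.5 and 0.25, and 5 of 5770 unchanged genes were called. Both simulated groups had 1 spread, taken from the untreated libraries (dispersion 0.009), and the changed genes had at least 10 FPKM untreated. The real H55 libraries differed more among themselves, with median absolute log2 differences of 0.17 to 0.31 per pair against 0.12 to 0.18 among untreated libraries. Recovery of genes with a wider spread or lower level was therefore not tested.

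Alternatives to the main processing were a pseudocount of 0.1, no filter on low values, the replicate number as a block, leaving out each library in turn, scaling factors computed without the 20 most abundant genes, and the estimated correlation in camera. Alternatives added after the data were examined were median-of-ratios scaling between libraries, a mean of at least 10 FPKM, a robust spread in limma, limma-voom on the recovered reads, limma's treat against a 2-fold change, and leaving out untreated replicate 2 and H55 replicate 1 together. Fold changes of the values as deposited lay below those after median-of-ratios scaling by a log2 shift of -0.31, and list counts are given under both scalings. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for read recovery, intervals and figures.

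Without strand information, reads of overlapping or antisense gene pairs cannot be assigned to a gene with certainty. Near-identical copies, such as members of the SAP, ALS, HGT and TLO families, transposase genes and paired ribosomal protein or histone genes, may share reads, and their separate values are uncertain. Intervals that rest on read numbers cover counting error only.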

Results

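RNA levels were measured in Candida albicans SC5314, the reference laboratory strain of this pathogenic yeast, after growth in RPMI medium with or without H55. H55 is a compound known as an inhibitor of Erg6, the sterol methyltransferase of ergosterol synthesis. The data comprised 3 untreated libraries and 3 libraries from cells exposed to 8 µM H55 for 6 h. Depth was 41591618, 38763292 and 37456782 reads in untreated replicates 1, 2 and 3 and 37701921, 47452006 and 46177360 reads in H55 replicates 1, 2 and 3. Nothing in the sources used here says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low values. Levels are in FPKM, given as mean ± SD with n = 3 libraries per group, and a value after ± beside a log2 fold change is its standard error.

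The comparison of H55 with untreated cells asked how gene expression in this strain responds to the compound. With H55, 71 of 72 cytosolic ribosomal protein genes and 77 of 83 ribosome biogenesis genes fell, as did 36 of 48 genes of cell wall synthesis and 41 of 66 genes of amino acid biosynthesis. In the list of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, 23 of 31 genes rose. Changes on the log2(FPKM + 1) scale were ranked among genes with a symbol, at least 10 FPKM on average and non-overlapping groups. The largest fall was that of SKO1, a transcription factor of the osmotic and cell wall stress responses, from 301.4 ± 20.9 to 12.4 ± 0.91 FPKM. PRA1 lay close to it (log2 fold change -4.44 ± 0.98 against -4.49 ± 0.12). The largest rise was that of JEN2, a dicarboxylate transporter, from 3.02 ± 1.27 to 92.1 ± 67.2 FPKM. HGT17 and AQY1 lay within its standard error (4.21 ± 0.30 and 4.08 ± 0.61 against 4.28 ± 0.55), so these ranks are not secure. The scale understates the change of genes near 0 such as OP4. Genes of ergosterol synthesis went both ways, with 6 of 24 higher and 10 lower, and ERG6 itself measured 249.5 ± 39.9 FPKM untreated and 283.3 ± 66.5 FPKM with H55.

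Of 5993 genes tested, 3722 changed (limma, adjusted p under 0.05), 1124 upward and 2598 downward, and 1635 of them changed at least 2-fold on the fitted scale, 371 upward and 1264 downward. For 4162 genes (69.4%) no untreated library overlapped an H55 library, against 10% by chance for 3 against 3. The median log2 fold change of all tested genes was -0.29. After median-of-ratios scaling, which sets this median near 0, 3749 genes changed, 1848 upward and 1901 downward, and 1430 changed at least 2-fold, 673 upward and 757 downward, so that the share of upward changes among all changed genes was 49.3% in place of 30.2%. All 1124 genes higher as deposited were also higher after scaling, and 1901 of the 2598 lower genes stayed lower. The direction of changes smaller than about the shift of -0.31 between the scalings therefore rests on the scaling, and each list is given under both. The median also varied with level, from -0.61 in the lowest to -0.05 in the highest of 5 equal groups of genes by level. Scaling by 1 factor per library does not remove this trend. List counts and camera results were not adjusted for it, so falls of low-level members include it under both scalings. Against a minimum change of 2-fold tested by limma's treat, 353 genes passed.

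On the first principal component, which held 81.6% of the variance, untreated libraries lay at -34.2, -41.6 and -31.4 and H55 libraries at 31.4, 37.1 and 38.8. The second held 10.9% and set H55 replicate 1, at 25.8, apart from H55 replicates 2 and 3, at -18.2 and -5.3. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.989 to 0.994 within the untreated group, 0.969 to 0.991 within H55 and 0.896 to 0.934 between the groups. Ribosomal RNA took 1.07% of reads in untreated replicate 2 and 0.0463% to 0.115% in the other libraries. The 20 most abundant genes took 19.2% to 19.9% of reads in untreated libraries and 24.8% to 30.0% in H55 libraries.

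**Figure D1:**
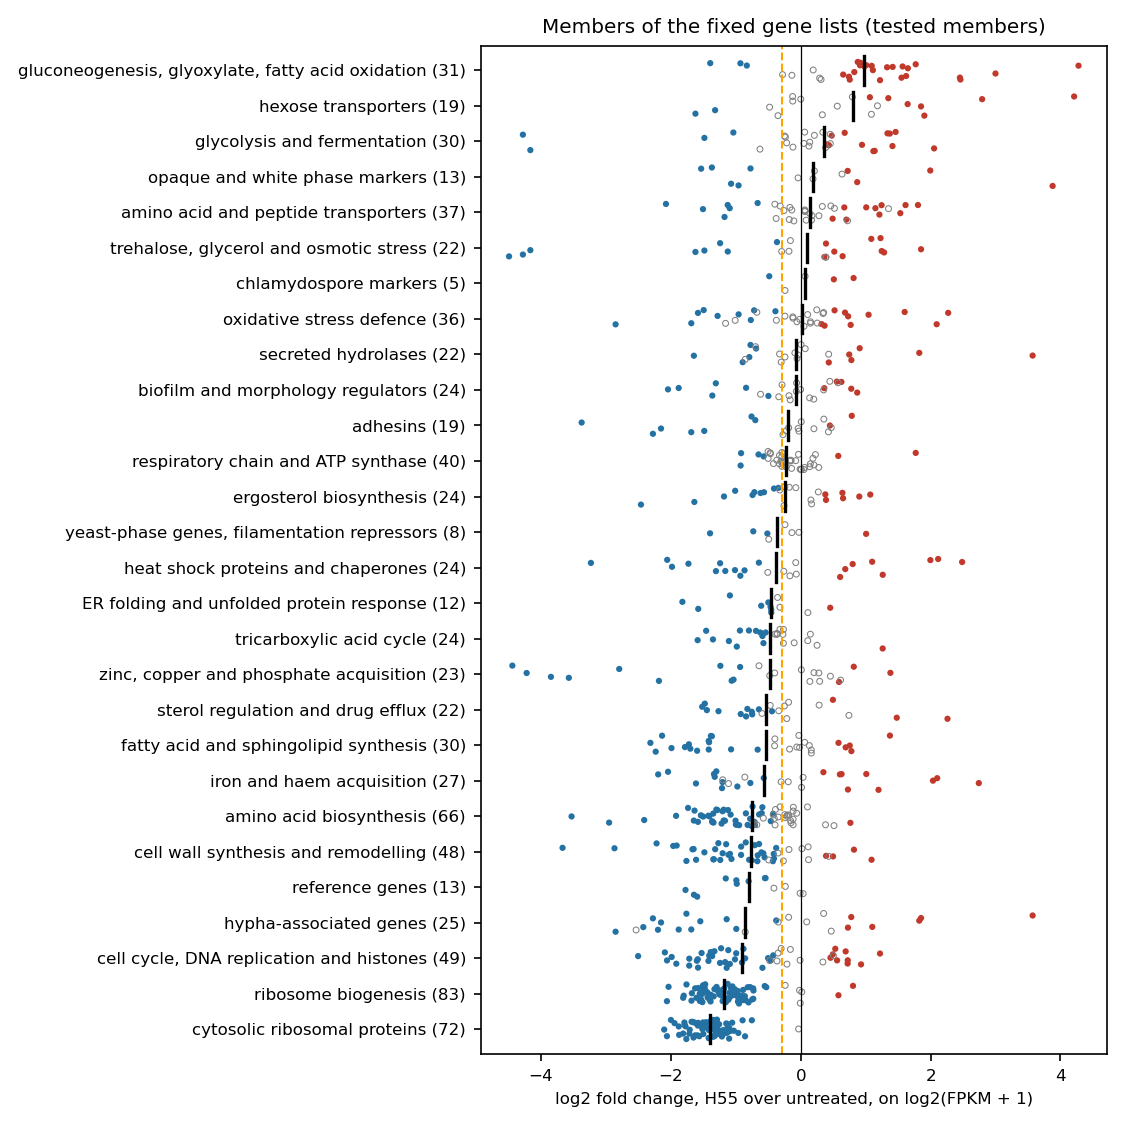
Log2 fold changes (H55 over untreated, on log2(FPKM + 1)) of the tested members of the 28 gene lists. Each point is 1 gene, red where it rose, blue where it fell and open where it did not pass the threshold, black bars mark list medians and the dashed line marks the median of all tested genes at -0.29. Medians run from -1.4 for cytosolic ribosomal proteins to 0.98 for gluconeogenesis, the glyoxylate cycle and fatty acid oxidation.

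The 12 largest rises among genes with a symbol, at least 10 FPKM on average and non-overlapping groups included several transporters. After JEN2 (CAALFM_C404030WA, log2 fold change 4.28 ± 0.55) came the hexose transporter family member HGT17 (CAALFM_C401070WA, 4.21 ± 0.30), the aquaporin AQY1 (CAALFM_CR02920CA, 4.08 ± 0.61), the adherence regulator TRY4 (3.59 ± 0.43), the secreted aspartyl protease SAP4 (3.57 ± 0.56), the transposase gene CIRT4B (3.25 ± 0.25) and the predicted glucoamylase GCA2 (3.11 ± 0.29). The carnitine acetyltransferase CTN3 (3 ± 0.27), HPD1 of propionate breakdown (2.93 ± 0.32), the sugar transporter HXT5 (2.79 ± 0.38) and the ferric reductase FRP1 (2.74 ± 0.33) followed. OP4, a marker of the opaque phase, had 2 reads over the 3 untreated libraries and 3618 over the H55 libraries, a ratio per sequenced read of 1622 with a 95% interval of 449 to 13402 that covers counting error only. Its H55 libraries held 190, 692 and 2736 reads, and the ratio was 610 without H55 replicate 3 and 1050 without untreated replicate 1, while untreated replicate 3 held both untreated reads. Limma adjusted p-values of these 12 genes lay between 7.02e-05 and 0.00147. CIRT4B has near-identical copies and SAP4 near-identical relatives, so their separate values are uncertain.

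Among the 12 largest falls by the same rule, SKO1 (CAALFM_C103770WA) fell by 4.49 ± 0.12 (limma adjusted p = 1.53e-06). RHR2, the glycerol-3-phosphatase, went from 5220 ± 918 to 301.6 ± 192.5 FPKM and GPD2, a glycerol-3-phosphate dehydrogenase, from 2977 ± 588 to 174.9 ± 82.6 FPKM. The secreted zinc-binding protein PRA1 (-4.44 ± 0.98) and the zinc transporters ZRT2 (-4.22 ± 0.52) and ZRT1 (-3.85 ± 0.80) fell, as did the phosphate transporter PHO84 (-3.57 ± 0.22), the ATP sulfurylase MET3 (-3.53 ± 0.39) and the carbonic anhydrase NCE103 (-3.47 ± 0.28). The remaining falls were those of the glucan synthesis protein SKN1 (-3.67 ± 0.20), the cell wall protein PGA6 (-3.38 ± 0.22) and MRV8 (-3.28 ± 0.17). Limma adjusted p-values of the falls were at most 0.00474, the value of PRA1, whose untreated libraries spread widely (908 ± 676 FPKM). Of the 131 genes named by the fixed rule, 125 were past the threshold, and all 125 had groups of libraries that did not overlap. The rule's first part required both, and its second part took list members with the smallest p. These counts therefore follow largely from the selection.

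**Figure D2:**
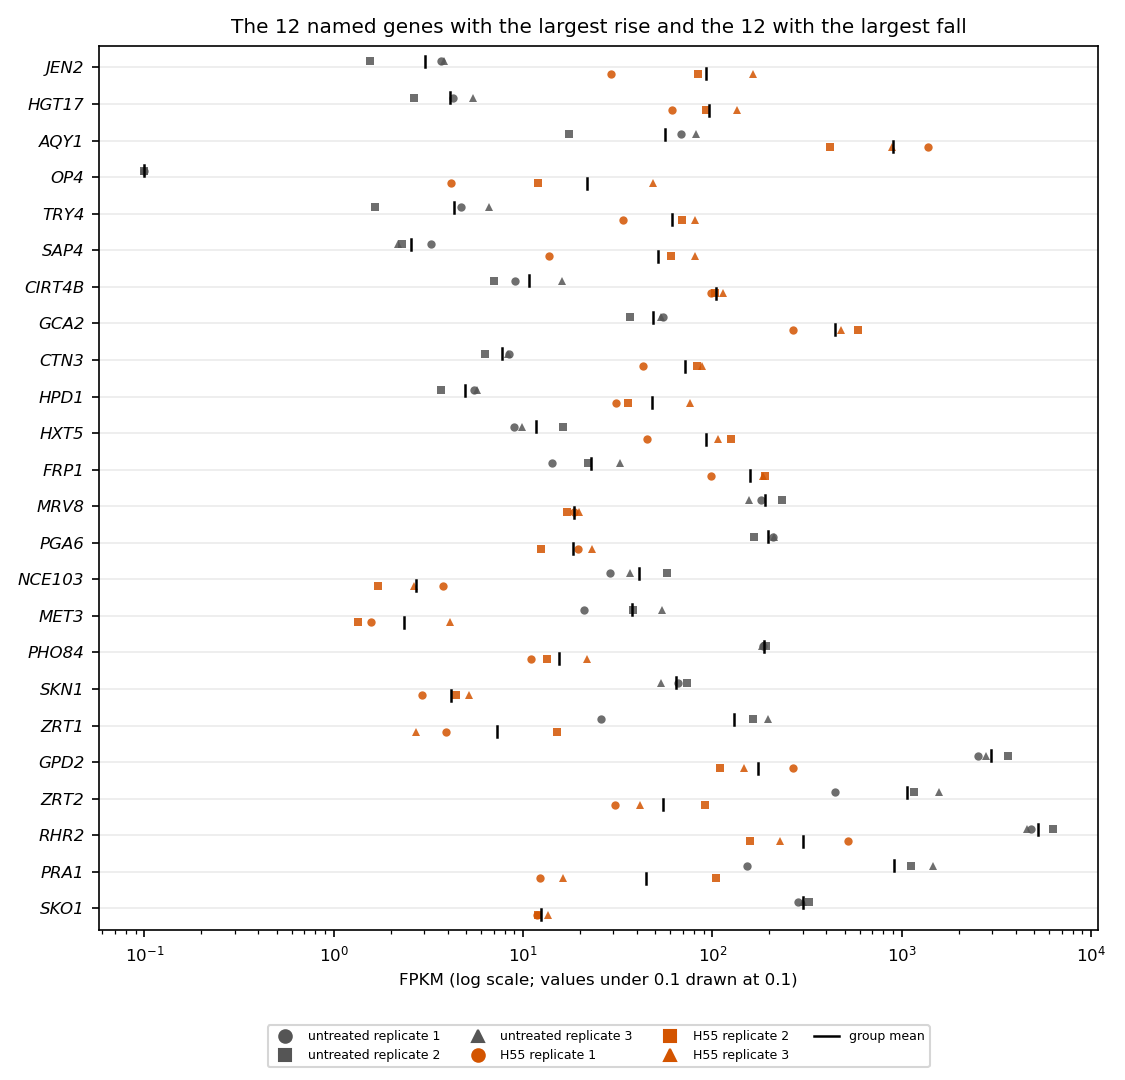
FPKM (log axis) in each library of the 12 genes with the largest rise and the 12 with the largest fall among those eligible by the naming rule. Grey points are untreated and orange points H55 libraries, with marker shapes for replicates, black bars for group means and values under 0.1 drawn at 0.1. In each gene all H55 points lie on one side of all untreated points, as the naming rule requires, and for SKO1 the group means are 301.4 and 12.4 FPKM.

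In the ergosterol biosynthesis list, 6 of 24 members were higher and 10 lower, 16 also when adjusted over the list alone, and after median-of-ratios scaling the balance turned, with 8 higher and 5 lower. ERG2, the sterol isomerase, fell from 89.6 ± 25.3 to 15.1 ± 1.83 FPKM (-2.46 ± 0.20). Mevalonate kinase ERG12 (-1.64 ± 0.21), HMG-CoA reductase HMG1 (-1.18 ± 0.12) and the sterol methyl oxidase ERG25 (-1.01 ± 0.19) fell as well. Squalene epoxidase ERG1 rose from 277.8 ± 13.9 to 584.5 ± 20.4 FPKM (1.07 ± 0.12), the sterol desaturase ERG3 from 80.3 ± 19.0 to 148.5 ± 6.03 FPKM (0.90 ± 0.17) and the lanosterol demethylase ERG11 from 401.9 ± 53.4 to 625.2 ± 45.3 FPKM (0.64 ± 0.15). These calls had limma adjusted p-values from 8.25e-05 to 0.00565. ERG251, listed beside ERG25, rose from 636.8 ± 26.85 to 837.1 ± 91.1 FPKM (0.39 ± 0.14, limma adjusted p = 0.036, and 0.70 after scaling). Its level was above that of ERG25 (109.6 ± 14.8 FPKM untreated), and it was chosen after its value was seen. ERG6 did not pass (0.17 ± 0.20, limma adjusted p = 0.48), and its difference ran from -0.01 without H55 replicate 1 to 0.32 without H55 replicate 2 and was 0.48 after scaling (adjusted p from 0.0802 to 0.967 over all alternatives). The sterol regulator UPC2 did not pass either (-0.34 ± 0.26, limma adjusted p = 0.274), but did without H55 replicate 1 (-0.61, adjusted p = 0.0164), while its difference was -0.05 without H55 replicate 2 and -0.04 after scaling, where adjusted p was highest at 0.919.

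In the list of sterol regulation and drug efflux, 3 of 22 members rose and 11 fell (15 past the threshold when adjusted over the list alone), against 5 and 7 after scaling. The efflux pump genes MDR1 (-1.27 ± 0.13), FLU1 (-1.45 ± 0.15) and CDR1 (-0.82 ± 0.12) and the MDR1 regulator MRR1 (-1.52 ± 0.21) fell, with limma adjusted p-values of at most 0.000602. CDR1 measured 118.2 ± 4.98 FPKM untreated and 66.5 ± 4.48 FPKM with H55, and its log2 fold change was -0.52 after scaling. The members that rose were the transporter genes CDR4 (2.26), CDR11 (1.48) and QDR2 (0.50), which were chosen after their values were seen.

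Among hypha-associated genes, 12 of 25 fell and 6 rose (19 past the threshold when adjusted over the list alone), against 10 and 7 after scaling. The surface transglutaminase substrate HWP1 measured 1045 ± 228 FPKM untreated and 338.8 ± 263.0 FPKM with H55 (-2.15 ± 0.75, limma adjusted p = 0.0352), and the adhesin and invasin ALS3 went from 359.1 ± 34.0 to 100.4 ± 82.5 FPKM (-2.28 ± 0.63, limma adjusted p = 0.0139). The hyphal regulator UME6 fell by 1.88 ± 0.47 (limma adjusted p = 0.00825), the pH-responsive glucan remodelling enzyme PHR1 by 1.76 ± 0.15, the wall protein RBT1 by 1.69 ± 0.16 and the GPI-anchored protein PGA13 by 2.43 ± 0.23. ECE1, which encodes the precursor of candidalysin, did not pass (-2.54 ± 0.997, limma adjusted p = 0.0542), although each H55 library lay under each untreated library. The members that rose included SAP4 and the hexose transporter HGT2 (1.85 ± 0.19).

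H55 replicate 1 held the lowest levels of HWP1, ALS3, ECE1 and UME6. ECE1 was at 52.6 FPKM there against 1443 and 519.5 in H55 replicates 2 and 3 and 1605 to 2232 in untreated libraries, and HWP1 at 54.6 against 573.7 and 388.1. Without H55 replicate 1 the differences were -1.12 for HWP1, -1.44 for ALS3 and -1.20 for ECE1, each past the threshold, and ECE1 was also past it without H55 replicate 2 (-3.57, limma adjusted p = 0.00636), its highest adjusted p being 0.139 without untreated replicate 2. HWP1 lost its call without untreated replicate 1, 2 or 3 (adjusted p = 0.0791, 0.111 and 0.0607) and after median-of-ratios scaling (adjusted p = 0.0606) and with a robust spread (adjusted p = 0.0787), and ALS3 lost it without untreated replicate 2 (adjusted p = 0.0524). The lowest adjusted p of either came without H55 replicate 1, at 0.00205 for HWP1 and 0.00125 for ALS3. The median of the list was -0.86 and its mean -0.58, whereas camera, which weighs each gene by its error, gave the direction as up (adjusted p = 0.832).

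Of 8 yeast-phase genes and filamentation repressors, the repressor NRG1 rose from 138.3 ± 6.23 to 286.6 ± 78.8 FPKM (1.01 ± 0.21, limma adjusted p = 0.00342). RHD1 (-1.40 ± 0.21), the repressor RFG1 (-0.73 ± 0.18) and the wall protein RHD3 (-0.51 ± 0.19) fell, of which RHD1 kept its call after scaling and the other two did not (adjusted p = 0.0722 and 0.375). RHD3 (limma adjusted p = 0.0433) also lost its call without untreated replicate 1 or 3 or H55 replicate 2 or 3 (adjusted p = 0.165, 0.139, 0.109 and 0.0868), its lowest adjusted p over all alternatives being 0.00221. The yeast wall protein YWP1 did not pass (-0.03 ± 0.89, limma adjusted p = 0.979). Its H55 libraries ran from 3.51 FPKM in H55 replicate 2 to 80.6 FPKM in H55 replicate 1. Its difference was -1.02 without H55 replicate 1, 1.07 without H55 replicate 2 and 0.26 after scaling. Adjusted over the list alone, 3 members passed, and after scaling 1 rose and 1 fell. Among 24 biofilm and morphology regulators, 6 fell and 5 rose (11 adjusted over the list alone), against 5 and 10 after scaling. The transcription factor RFX2 (-2.05 ± 0.25), the kinase CEK1 (-1.36 ± 0.14) and its downstream factor CPH1 (-1.31 ± 0.14) fell. The factor CZF1 rose (0.87 ± 0.17), as did BRG1 (0.78), CYR1 (0.63), TPK2 (0.56) and SFL2 (0.36), which were chosen after their values were seen.

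**Figure D3:**
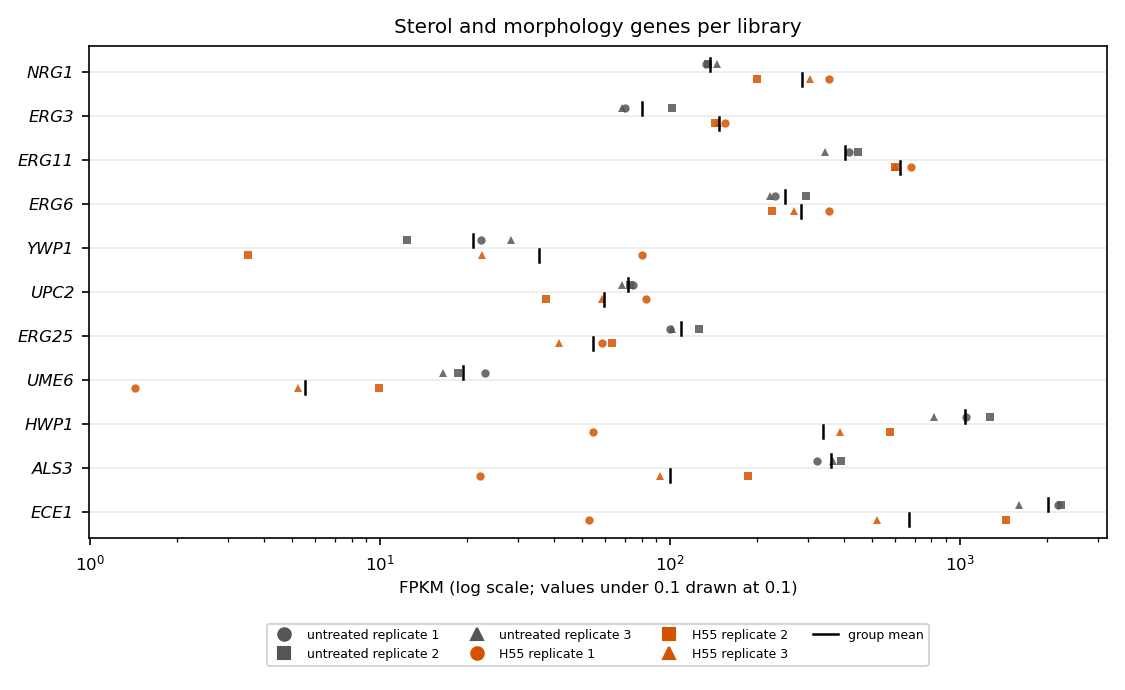
FPKM (log axis) in each library of the fixed sterol and morphology genes. Grey points are untreated and orange points H55 libraries, with marker shapes for replicates and black bars for group means. H55 replicate 1 has the lowest HWP1, ALS3, ECE1 and UME6 values, with ECE1 at 52.6 FPKM.

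In the adhesin list 10 genes did not pass, with 7 of 19 lower and 2 higher (9 adjusted over the list alone), against 6 and 4 after scaling. PGA6 fell from 195.8 ± 25.5 to 18.4 ± 5.46 FPKM, and RBT1, PGA32 (-1.49 ± 0.26) and PGA1 (-0.76 ± 0.15, and -0.45 after scaling) also fell. IFF6 (0.79) and ALS9 (0.45) rose and were chosen after their values were seen. In the list of secreted hydrolases 6 of 22 rose and 5 fell (11 adjusted over the list alone), against 7 and 5 after scaling. The proteases SAP4 (3.57 ± 0.56) and SAP99 (0.91 ± 0.13) rose and the lipase LIP8 (-1.65 ± 0.19) and the protease SAP10 (-0.89 ± 0.14, and -0.60 after scaling) fell. The other falls, chosen after their values were seen, were those of PLB1 (-0.79), SAP3 (-0.77) and PLB2 (-0.69).

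Of 48 genes of cell wall synthesis and remodelling, 36 fell and 4 rose (41 past the threshold adjusted over the list alone), and 29 fell and 5 rose after scaling. Camera gave an adjusted p of 0.00249 with the preset correlation and an adjusted p = 0.62 with an estimated correlation. SKN1 fell from 64.2 ± 10 to 4.18 ± 1.14 FPKM, the chitin synthase activator CHS4 from 80.7 ± 6.33 to 19.99 ± 2.40 FPKM, the mannosyltransferase MNT2 from 31.9 ± 1.99 to 7.77 ± 0.93 FPKM and PHR1 from 708.2 ± 72.5 to 208.5 ± 25.4 FPKM. The members that rose, chosen after their values were seen, were PHR3 (1.09), the chitinase CHT3 (0.82), GSL2 (0.50) and CHS5 (0.39).

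Among genes of fatty acid and sphingolipid synthesis, 15 of 30 fell and 5 rose (20 adjusted over the list alone), against 13 and 7 after scaling. The fatty acid desaturase FAD2 fell from 371.3 ± 56.3 to 73.3 ± 4.52 FPKM, the ceramide synthase LAC1 by 2.14 ± 0.14, acetyl-CoA carboxylase ACC1 by 1.78 ± 0.13 and the elongase FEN12 by 1.70 ± 0.14, with limma adjusted p-values of at most 7.8e-05. The sphingolipid hydroxylases SUR2 (1.37) and SCS7 (0.76) rose with ORM1 (0.78), SPT23 (0.69) and SLD1 (0.58), all chosen after their values were seen.

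Of the lists, the 1 with the highest median covers carbon sources other than sugars. In the list of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, 23 of 31 rose and 3 fell, and 25 rose and 3 fell after scaling, with 26 past the threshold adjusted over the list alone. The list's median was 0.98, which is 1.27 above the median gene. Camera gave an adjusted p of 1.19e-08 with the preset correlation and an adjusted p = 0.62 with an estimated correlation. JEN2 and CTN3 rose most, the peroxisomal ubiquitin-conjugating enzyme PEX4 went from 57.2 ± 1.67 to 169.9 ± 8.56 FPKM (1.55 ± 0.12) and the peroxisomal malate dehydrogenase MDH1-3 from 133.1 ± 10.9 to 288.5 ± 21.2 FPKM (1.11 ± 0.13). The members that fell were the fatty acid oxidation regulator CTF1 (-1.39 ± 0.16) and, chosen after their values were seen, CRC1 (-0.93) and INO2 (-0.83).

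Of 30 genes of glycolysis and fermentation, 12 rose and 4 fell (15 adjusted over the list alone), against 16 and 4 after scaling. By camera the list had an adjusted p of 0.00249, or adjusted p = 0.62 with an estimated correlation. The aldehyde dehydrogenase ALD6 rose from 11.3 ± 0.98 to 50.8 ± 12.7 FPKM and the glucokinase GLK4 from 203.5 ± 26.7 to 543.2 ± 70.9 FPKM. The members that fell were RHR2 and GPD2, with GPD1 (-1.48) and the regulator PDC2 (-1.04), the latter pair chosen after their values were seen. RHR2, GPD2 and GPD1 make glycerol from a glycolytic intermediate.

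Among 19 hexose transporter genes, 7 rose and 2 fell (8 adjusted over the list alone), against 11 and 2 after scaling. The camera test gave an adjusted p of 0.00669, or adjusted p = 0.62 with an estimated correlation. HGT6 rose from 844.4 ± 154.7 to 3195 ± 781 FPKM and HGT2 from 513.7 ± 121.7 to 1822 ± 79.2 FPKM, while HGT10, known as a glycerol permease, fell from 180.8 ± 29.5 to 58.5 ± 12.3 FPKM. The other fall was that of HGT20 (-1.32), chosen after its value was seen. In the tricarboxylic acid cycle list 12 of 24 fell and 1 rose (13 adjusted over the list alone), against 6 and 4 after scaling. The succinate dehydrogenase subunit SDH4 (-1.35 ± 0.12) and the pyruvate dehydrogenase subunit PDB1 (-1.11 ± 0.15) fell, and the malate dehydrogenase MDH1 rose from 454.4 ± 12.9 to 1093 ± 92.6 FPKM. Of 40 genes of the respiratory chain and ATP synthase, 34 did not pass. The lactate dehydrogenase CYB2 rose (1.77 ± 0.26) with COX19 (0.58), and the ATP synthase subunits ATP19 (-0.93 ± 0.19), ATP20 (-0.92 ± 0.18, and -0.61 after scaling) and ATP7 (-0.57 ± 0.18) fell with COX11 (-0.65), COX19 and COX11 being chosen after their values were seen. After scaling 8 rose and 2 fell and the list's median moved from -0.23 to 0.07. ATP7 (limma adjusted p = 0.0249) lost its call after scaling and without untreated replicate 1 or 2 or H55 replicate 2 or 3 (adjusted p = 0.26, 0.0678, 0.0862, 0.068 and 0.0981), its lowest adjusted p being 0.00104 without H55 replicate 1. Adjusted over the list alone, 3 members passed.

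The falls in ribosomal genes held for nearly every member. Of 72 cytosolic ribosomal protein genes 71 fell and none rose, with a median of -1.4, which is 1.11 below the median gene, and 70 fell after scaling. RPL11 went from 2388 ± 259 to 562.2 ± 128.6 FPKM, RPS7A from 1671 ± 24.2 to 403.2 ± 66.0 FPKM and RPL7 from 57.5 ± 4.40 to 23.1 ± 1.78 FPKM. The member that did not pass was RPS27A (-0.03), chosen after its value was seen. Of 83 ribosome biogenesis genes 77 fell and 2 rose, and 75 fell and 2 rose after scaling. The RNA polymerase I subunits RPA135 (-1.68 ± 0.14) and RPA34 (-1.61 ± 0.13), RPC40, a subunit shared by RNA polymerases I and III (-1.58 ± 0.12), and the ribosome assembly factor NOC2 (-1.80 ± 0.15) fell. PWP2 (0.58) and CGR1 (0.81) rose, and SOF1 (-0.24), RRP8 (-0.02), NOP14 (-0.01) and RPF1 (0.02) did not pass, all chosen after their values were seen. Adjusted over the list alone, 71 and 79 members of these lists passed. Camera gave adjusted p-values of 5.5e-11 for the ribosomal proteins and 6.91e-11 for ribosome biogenesis, which became adjusted p = 0.72 and adjusted p = 0.62 with an estimated correlation.

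Genes of amino acid biosynthesis fell in 41 of 66 cases and rose in 1, that of LEU1 (0.77), chosen after its value was seen (36 and 3 after scaling, and 43 past the threshold adjusted over the list alone). Camera gave an adjusted p of 0.00249, or adjusted p = 0.82 with an estimated correlation. The named members belong to methionine and cysteine synthesis and fell, MET3 from 37.8 ± 16.7 to 2.34 ± 1.53 FPKM, CYS3 from 178.2 ± 24.2 to 53.3 ± 10.9 FPKM, MET1 from 17.8 ± 1.71 to 5.63 ± 0.34 FPKM and STR2 from 73.1 ± 7.38 to 31.5 ± 0.78 FPKM. Of 37 amino acid and peptide transporter genes, 10 rose and 6 fell (16 adjusted over the list alone), against 15 and 6 after scaling. The list's camera adjusted p was 0.0216, which was 0.0664 after scaling, 0.0502 without H55 replicate 3, 0.0775 among genes averaging at least 10 FPKM, lowest at 0.0127 without H55 replicate 1, and adjusted p = 0.62 with an estimated correlation. The permease AGP2 fell from 885.6 ± 21.8 to 210.8 ± 31.8 FPKM, the ammonium permease MEP1 by 1.51 ± 0.19 and the choline permease family member HNM1 by 1.17 ± 0.13, and HNM3 rose by 1.25 ± 0.15.

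In the list of cell cycle, DNA replication and histone genes, 31 of 49 fell and 9 rose (43 past the threshold adjusted over the list alone), against 27 and 11 after scaling. The cyclin PCL2 fell from 29.0 ± 6.49 to 4.24 ± 0.84 FPKM, the cohesin subunits SMC1 and SMC3 by 1.99 ± 0.15 and 1.58 ± 0.13 and the G1 regulator SWI6 by 1.72 ± 0.14, with limma adjusted p-values of at most 8.15e-05. Camera gave an adjusted p of 0.0681, and 0.0204 without H55 replicate 3, 0.0371 without untreated replicate 1, 0.0234 after scaling and adjusted p = 0.82 with an estimated correlation.

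Stress genes went both ways. Among 36 genes of oxidative stress defence 10 rose and 9 fell (19 adjusted over the list alone), against 14 and 5 after scaling. Catalase CAT1 rose from 162.1 ± 3.53 to 800.8 ± 189.3 FPKM and the glutathione peroxidase GPX3 from 29.1 ± 3.62 to 129.6 ± 31.2 FPKM, while thioredoxin reductase TRR1 fell from 387.6 ± 46.5 to 136.3 ± 6.54 FPKM and the old yellow enzyme EBP1 by 1.69 ± 0.16. Of 24 heat shock and chaperone genes 8 rose and 11 fell (19 adjusted over the list alone), against 8 and 10 after scaling. The disaggregase HSP104 rose from 142.2 ± 26.1 to 564.4 ± 24.9 FPKM. The chaperones YDJ1 (-2.06 ± 0.18) and MSI3 (-1.98 ± 0.22) and the Hsp90 cochaperone HCH1 (-1.73 ± 0.19) fell. Of 12 genes of endoplasmic reticulum folding 8 fell and 1 rose (10 adjusted over the list alone), against 3 and 2 after scaling. The translocon subunit SEC62 (-1.82 ± 0.14), JEM1 (-1.58 ± 0.23), ERV46 (-1.09 ± 0.13) and ERV29 (-0.61 ± 0.15) fell, of which ERV29 lost its call after scaling (adjusted p = 0.122, the highest of its alternatives, with 0.000758 the lowest), and ERO1 rose (0.45), chosen after its value was seen. In the list of trehalose, glycerol and osmotic stress 9 of 22 rose and 8 fell (18 adjusted over the list alone), against 11 and 7 after scaling. SKO1, RHR2, GPD2 and the kinase PBS2 of the osmotic stress pathway (-1.12 ± 0.12) fell. The median of this list was 0.10 and its mean -0.46.

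Metal and phosphate genes changed in both directions. Of 27 genes of iron and haem acquisition 9 rose and 11 fell (20 adjusted over the list alone), against 9 and 10 after scaling. FRP1 rose from 22.9 ± 9.17 to 157.4 ± 51.1 FPKM and the haem-binding surface protein PGA10 from 26.9 ± 6.66 to 118.0 ± 23.1 FPKM, while the iron permease FTR2 fell from 183.0 ± 30.1 to 40.4 ± 13.6 FPKM and the regulator SEF1 by 1.61 ± 0.15. Of 23 genes of zinc, copper and phosphate acquisition 10 fell and 3 rose (13 adjusted over the list alone), against 10 and 6 after scaling. ZRT2 went from 1060 ± 573 to 54.6 ± 32.4 FPKM, PHO84 from 186.6 ± 4.62 to 15.4 ± 5.70 FPKM and the phosphate transporter PHO89 from 11.1 ± 1.53 to 1.67 ± 0.49 FPKM. GIT3, a transporter of glycerophosphocholine, rose from 44.3 ± 10.3 to 114.9 ± 1.54 FPKM, with VTC4 (0.82) and PHO113 (0.59) chosen after their values were seen.

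Markers of other cell forms gave small groups. Of 13 opaque and white phase markers 4 rose and 5 fell (9 adjusted over the list alone), against 6 and 4 after scaling. WH11, a white phase marker, rose from 12570 ± 2583 to 49870 ± 8153 FPKM, and the opaque marker OP4 and CZF1 rose too, with the G protein subunit STE4 (0.72), chosen after its value was seen. AHR1 (-1.53 ± 0.20), the pheromone receptor STE3 (-1.37 ± 0.15) and the G protein subunit CAG1 (-0.96 ± 0.16) fell, together with MFA1 (-1.07) and SAP3, both chosen after their values were seen. SAP3 is listed as an opaque phase marker like OP4, but went the other way. SAP1, another opaque marker chosen after its value was seen, measured 6.04 ± 0.73 FPKM untreated and 5.93 ± 1.54 FPKM with H55. By camera the opaque and white phase list had an adjusted p of 0.368, which was 0.0369 among genes averaging at least 10 FPKM and 0.639 without H55 replicate 1. The list pools markers of both phases with mating genes, so its counts and its camera result say nothing about either phase. Among 5 genes listed as chlamydospore markers CSP37 (0.81 ± 0.15) and CSP1 (0.51 ± 0.16) rose and PGA63 (-0.49 ± 0.17) fell. Adjusted over the list alone 3 passed, and after scaling 2 rose and 0 fell. The list came from general knowledge, and whether each member is particular to chlamydospores was not tested. CSP1 (limma adjusted p = 0.0233) lost its call without untreated replicate 1 or 2 or H55 replicate 3 (adjusted p = 0.0586, 0.0814 and 0.0828), its lowest adjusted p being 0.00449 after scaling. PGA63 (limma adjusted p = 0.0367) lost it after scaling (adjusted p = 0.403) and without any library except H55 replicate 1 (adjusted p from 0.0701 to 0.116), and was at 0.00482 without that library.

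Of 13 reference genes often used for normalisation 9 fell and none rose (9 adjusted over the list alone), against 6 and 0 after scaling, with a median of -0.8. GNA1 (-1.65 ± 0.18), RPP2B (-1.78 ± 0.23), PMA1 (-1.60 ± 0.21) and TUB2 (-1.16 ± 0.24) fell, whereas ACT1, chosen after its value was seen, did not pass (0.04). By camera the reference genes had an adjusted p of 0.256, which was 0.0499 without H55 replicate 1 and adjusted p = 0.82 with an estimated correlation. The most abundant transcripts were those of CUP1, TDH3 and ADH1 in untreated cells and CUP1, WH11 and TDH3 with H55. The metallothionein CUP1 measured 45830 ± 2250 and 59770 ± 27870 FPKM and the glyceraldehyde-3-phosphate dehydrogenase TDH3 38010 ± 980 and 41920 ± 7411 FPKM, and neither passed (limma adjusted p = 0.453 and 0.551). CUP1 passed without H55 replicate 1 (0.61, adjusted p = 0.0233), and its difference was -0.07 without H55 replicate 2 (adjusted p = 0.795), while that of TDH3 was 0.26 without H55 replicate 2 and 0.44 after scaling. ADH1, the main alcohol dehydrogenase, rose from 29940 ± 1278 to 40590 ± 4388 FPKM (limma adjusted p = 0.0384) and lost this call without untreated replicate 1, 2 or 3 or H55 replicate 3 (adjusted p = 0.0975, 0.111, 0.122 and 0.121), and was at 0.74 after scaling (adjusted p = 0.00747).

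Camera compares each list with the other genes, so its direction is relative to the general shift. It called 8 of 28 lists with the preset correlation, each given with its list, and none with an estimated correlation, where the lowest adjusted p was 0.62. The other lists had preset adjusted p-values from 0.0681 to 0.853. The direction was up, against a median under 0, for the lists of ergosterol biosynthesis, hypha-associated genes, biofilm regulators, adhesins, secreted hydrolases, heat shock proteins, iron acquisition and the respiratory chain. For oxidative stress defence and for trehalose, glycerol and osmotic stress it was up against a mean under 0.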

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

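Median-of-ratios scaling, the limit of 10 FPKM, the robust spread, limma-voom, limma's treat and the joint leave-out of untreated replicate 2 and H55 replicate 1 were chosen after the data were seen, and the other alternatives before. No gene was called with opposite signs in any setting compared with the deposited values. Changed genes numbered 3703 with a pseudocount of 0.1, 3739 without a filter, 3678 with scaling factors computed without the 20 most abundant genes, 3749 with median-of-ratios scaling (3025 of the 3722 kept), 2925 among genes averaging at least 10 FPKM, 3706 with a robust spread, 3733 by limma-voom on recovered reads (3680 kept) and 3865 in the joint leave-out. Leaving out 1 library gave 3099 (without H55 replicate 3) to 4043 (without H55 replicate 1) changed genes and 8 to 9 gene lists, with 119 to 124 of the named genes past the threshold in place of 125. No pairing of the libraries by replicate number was visible, as same-numbered deviations correlated at 0.06, -0.02 and 0.12. Differently numbered ones ran from -0.17 to 0.12, so this check cannot exclude a pairing. The replicate block gave 3565 genes (3484 kept) and 9 lists. The block lost ADH1 (adjusted p = 0.101) and gained ECE1 (0.0303) and the cell cycle list (0.0406), and changed no other call of a named gene or list. Median-of-ratios scaling raised the genes higher from 1124 to 1848, treat lowered the genes changed at least 2-fold from 1635 to 353 because it tests against that size, and the estimated correlation left 0 of 8 lists. Scaling without the 20 most abundant genes ended the calls of RHD3, ATP7 and PGA63 (adjusted p = 0.146, 0.0879 and 0.143), the joint leave-out those of ADH1 and CSP1 (0.061 and 0.0731), and no filter that of ADH1 (0.0544), while UPC2 passed in the joint leave-out (0.0341). For the change in genes higher and these calls the cause was not tested. The estimated correlations of the 8 lists ran from 0.07 (cell wall synthesis) to 0.87 (cytosolic ribosomal proteins), each above the preset 0.01. They were estimated with 4 residual degrees of freedom, on which camera then also tested each list, which leaves little power. Lists with correlations not above the preset moved to a camera adjusted p of 0.62 too. These included endoplasmic reticulum folding (correlation 0, from 0.29) and fatty acid and sphingolipid synthesis (-0.01, from 0.368). The loss of the 8 lists is therefore weak evidence against them, and the part of the correlations in it was not tested. Directions that turned belonged to genes and lists not past the threshold, and the cause was not tested. The difference of YWP1 ran from -1.023 to 1.065 when 1 library was left out and was 0.093 without the 20 most abundant genes in the scaling and 0.261 with median-of-ratios scaling. That of ERG6 ran from -0.008 to 0.321 and that of CUP1 from -0.07 to 0.606 when 1 library was left out, and that of TDH3 was -0.014 in the joint leave-out. Camera's direction turned in some leave-outs of 1 library, with adjusted p from 0.575 to 0.998 for ergosterol biosynthesis, 0.735 to 0.981 for hypha-associated genes, 0.687 to 0.944 for yeast-phase genes, 0.748 to 0.981 for adhesins and 0.414 to 0.891 for the respiratory chain. It also turned for hypha-associated genes (adjusted p = 0.687), adhesins (0.871) and iron acquisition (0.871) with median-of-ratios scaling, for adhesins (0.977) and iron acquisition (0.977) among genes averaging at least 10 FPKM, and for adhesins (0.731) and the respiratory chain (0.618) in the joint leave-out. The planned count models (edgeR, DESeq2 and their variants) were not run, because the files hold no counts. Depth limits genes with few reads, as 1 read in 1 kb is worth 0.0211 to 0.0267 FPKM.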

Other observations

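The tests in this part were chosen after the results were seen, except the other splits of the libraries. Among families sharing a symbol prefix, with at least 8 tested genes, 48 were compared with the other genes. Of 15 PEX genes of peroxisome biogenesis 11 rose and 0 fell (14 and 0 after median-of-ratios scaling), with a median of 0.73 and PEX5 at 1.57. This set overlaps the list of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, which holds PEX4, PEX5, PEX11 and PEX13. All 10 MRPL genes of the mitochondrial ribosome fell (9 after scaling), with a median of -1.41, and of 12 TIM genes of mitochondrial protein import 11 fell and 1 rose (9 and 1 after scaling), with TIM23 at -1.79 and TIM22, the member that rose, at 1.16. All 9 ADE genes of purine synthesis fell (7 after scaling), with a median of -0.90 and ADE4 at -1.66. All 10 UTP genes of the small subunit processome fell (9 after scaling), a set that overlaps the ribosome biogenesis list.

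Of 11 TLO genes, a subtelomeric family related to a Mediator subunit, 7 rose and 3 fell (8 and 0 after scaling), with TLO9 at 1.27 and TLO10 at 1.21, and their near-identical copies make single values uncertain. Of 9 genes with the prefix RPN 4 rose and 0 fell (6 and 0 after scaling), with RPN8 at 0.69. They encode proteasome subunits except RPN4, a transcription factor of proteasome genes, which did not pass (-0.37). Camera adjusted p over the 48 families was 7.12e-06 for PEX, 0.0114 for MRPL and TLO, 0.0233 for ADE, 0.0322 for RPN and 0.0373 for TIM. In all 12 families passed with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.68.

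More genes were lower than higher with H55, and low-level genes fell more, with medians of -0.61 in the lowest and -0.05 in the highest of 5 equal groups of genes by level. A larger share of reads in abundant genes may account for part of the first imbalance. Without the 20 most abundant genes in the scaling, 39.2% of changed genes were higher in place of 30.2%, which leaves it open. For the trend with level it is argued against, since it would move genes of every level by 1 factor per library while these groups differed by 0.56 (bootstrap SD 0.04 over genes), and so is depth, since the lowest group differed by -0.59 between H55 replicate 1 and untreated replicate 3, of nearly equal depth. Fewer background reads with H55 stay open, with values below the filter summing to 0.86 of untreated, in ranges that overlap (94.8 to 125 untreated, 87.8 to 100 with H55), and so does an effect of the treatment itself.

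Untreated replicate 2 lay farther from H55 than the other untreated libraries. Across genes, which are not independent replicates, its differences from untreated replicates 1 and 3 correlated at -0.33 and -0.46 with that of H55 from the remaining untreated library, against -0.16 for replicate 1 minus 3 with H55 minus replicate 2. RNA of H55 cells mixed into untreated replicates 1 and 3 stays open, as 214 risen genes imply a median share of 12.7%, from 1.5% at the 10th percentile to 24.9% at the 90th, and untreated libraries differ beyond counting noise, so unequal shares exclude nothing. A difference in growth state stays open too, since ribosomal protein genes minus gluconeogenesis genes gave 0.3 in untreated replicate 2 against 1 and 3, but H55 moves both lists the other way and any library lying away from it would show that sign. This library also held 1.07% of reads as ribosomal RNA.

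H55 replicates 2 and 3 held more hypha-associated RNA than H55 replicate 1, with list medians of -0.93 and -0.66 for replicate 1 minus replicates 2 and 3. RNA of untreated cells mixed into H55 replicates 2 and 3 may have given this, as 6 fallen hypha genes imply a share of 35%. Over all 522 genes that fell at least 2-fold, the median implied share was -7.89%, with a 10th percentile of -40.8% and a 90th of 19%, where mixing needs a share above 0. The values argue against mixing as the only difference between H55 replicate 1 and H55 replicates 2 and 3. Mixing beside other differences stays open, because the H55 libraries differed beyond counting noise. A difference in the extent of filamentation between the treated cells stays open, and it was not tested.

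Other splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, with 10 splits in all. By limma the real split gave 3722 changed genes and the highest other 0, with 2 to 111 genes at an unadjusted p under 0.05 in the others, so that 1 of 10 splits gave as many. For genes changed at least 2-fold the real split gave 1635 and the highest other 0, again 1 of 10. Every other split places untreated and H55 libraries together, so their difference widens the spread within the groups. The low gene counts of the other splits are therefore no support for the real one. Camera called 8 lists in the real split and 12 in the highest other, and 6 of 10 splits gave as many.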
